A study of Mus musculus with 3 samples.

How the data were processed

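RNA from 3 samples labelled as spermatids of 30-day-old BALB/c mice was measured on the Affymetrix GeneChip Mouse Gene 1.0 ST array, a single-channel array with probes spread over the exons of each gene. Per the labels' protocols, testis tubules were cut and homogenised in a buffered glucose and lactate solution and passed through a cell strainer to give a suspension of single cells. No step that sorts or enriches a cell type is described there. Total RNA of 200 ng was labelled with the Ambion WT kit and biotin, per the labels' protocols. The 3 samples are numbered replicates of 1 group, and no control or second group was given, so no comparison between conditions exists. Nothing in the labels says that the replicates came from separate animals, and the spread between them may therefore be technical.

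The values are log2 probe set levels deposited by the authors, 1 column per sample. Per the series' design text, the authors applied Robust Multichip Average (RMA), which in its usual form corrects background, quantile normalizes the arrays and summarises the probes of each probe set by median polish, with Affymetrix Power Tools and annotation based on the mouse genome mm9. The version of that software is not given in the sources used here. The table held 35556 probe sets, control and unnamed ones included, and no scanner files were used here, so detection calls, probe sequences and GC content were not part of the work. The column medians were 7.17, 7.20 and 7.17 for replicates 1, 2 and 3, and the values were not centred. All 3 columns were used.

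Genes were named through the platform annotation, which named 1 gene for 21789 probe sets and several genes for 1621. The remaining 12146 probe sets were unnamed here. Symbols were updated by Entrez gene identifier to the reference gene table of assembly GRCm38.p6, which matched 21698 of the 21789 probe sets, and the array's own symbol was kept for the other 91. That table also gave the chromosome of each gene. Its coordinates were not used, because the authors' annotation was based on mm9. A gene's level was the median of the probe sets that name only that gene, which gave 19938 genes, of which 999 had more than 1 probe set. Probe sets of several genes named none.

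With 1 group, levels could only be set against a background and against other genes on the same arrays. The background level was the 95th percentile of the mean level of 211 genes not expected in testis, 167 vomeronasal receptor genes (Vmn1r and Vmn2r) and 44 hair keratin associated protein genes (Krtap), and it came to 7.98. The median of these genes was far lower at 4.77, with 4.54 for the vomeronasal receptor and 6.16 for the Krtap genes. A gene not called above background is therefore not shown to be absent. A gene was called above background with limma 3.58.1 in R 4.3.3, in an intercept model with empirical Bayes variances and a one-sided test of the mean against that level, with Benjamini-Hochberg adjustment over all genes at 0.05. Because 9173 genes (46.0%) had exactly the same level on all 3 arrays, their SD was 0 and the estimated prior carried 0.267 degrees of freedom. For such genes the test amounts to asking whether the level lies above the background level. On simulated data for this test, with 19938 genes and SDs drawn from the untied genes, 2 of 19738 genes at or below the level were called. Of 50 genes planted 0.5 above it 27 were called, and of 50 planted 1.0 above it 39. No simulated gene was tied and many lay below the level, so these rates do not describe the tied genes. Only 200 simulated genes lay above the level, which makes the adjustment stricter than with the many genes called in the data. The rates are therefore not the sensitivity of the test on the real data, for untied genes either. Tied genes made up 2844 of the 7295 genes called above background.

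Gene lists were fixed before the data were examined: 22 lists of markers of germ cell stages, somatic testis cells, blood, other tissues, and functional groups. Each list's mean was tested against the mean of all named genes with a two-sided permutation test over genes (100000 random lists of the same size), with Benjamini-Hochberg adjustment over the 22 lists. The smallest p that this can give is 1e-05. In 40 simulated lists of 20 genes per size, the test called 2 lists with no shift, 14 with a shift of 0.5, 28 with a shift of 1.0 and all 40 with a shift of 2.0 on the log2 scale. Another 13 pairs of lists were compared by permuting list membership in the same way, as were X-linked and autosomal genes. Retrogenes and their X-linked progenitors were compared with an exact sign-flip permutation test over pairs. Genes are not independent replicates, and these tests describe the genes on these arrays. Levels of different genes also depend on how well their probes bind, so comparisons were made between sets of genes. The highest and lowest members of a list and the single retrogene pairs are given to describe the sets, and their order is uncertain. For shifts between replicates, the median over a list's members of 1 replicate minus the mean of the other replicates was placed among 10000 random lists matched on mean level in 20 bins.

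Genes named in the text were chosen by a rule set before the data were examined: all members of the germ cell chromatin list, the 4 highest and the 2 lowest members of every other list, the retrogenes and progenitors, the 20 genes with the highest mean level and the 10 genes above background with the largest SD. Alternatives were another background percentile or family, the highest instead of the median probe set, quantile normalization run again, a common median, filters on low values, probe sets of several genes, medians instead of means, and leaving out each replicate. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The number of arrays limits the precision of each mean.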

Results

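The data comprised genome-wide RNA levels from 3 replicate arrays of cells labelled as spermatids, the haploid male germ cells formed by meiosis, from the testes of 30-day-old BALB/c mice. At this age the first wave of spermatogenesis has passed meiosis. The samples formed 1 group, so the questions open to the data were how closely the arrays agreed, which genes lay above background, and which germ cell and somatic genes made up the RNA. Values are RMA levels on the log2 scale, and errors are SDs over the arrays unless stated otherwise. Each difference described below for a list, a pair of lists or chromosome X had the same sign on all 3 arrays.

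The arrays gave nearly the same profile. Pearson's r over 35556 probe sets was 0.995 for replicates 1 and 2, 0.995 for replicates 1 and 3 and 0.992 for replicates 2 and 3, and Spearman's rho ranged from 0.991 to 0.995. These correlations are across probe sets within a pair of arrays, and probe sets are not independent replicates. The SD of the difference between a pair of arrays ranged from 0.20 to 0.26, and the pair of replicates 2 and 3 had 455 probe sets that differed by more than 1. Of the probe sets, 46.6% had exactly equal values in replicates 1 and 2, 51.4% in replicates 1 and 3, 38.8% in replicates 2 and 3, and 36.5% on all 3 arrays. The median SD of a gene was 0.0075, and 0.054 among genes whose values were not all tied. An SD of 0 in what follows means tied values, not an absence of error.

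Of 19938 named genes, 7295 (36.6%) were above the background level of 7.98 by limma's one-sided test with Benjamini-Hochberg adjustment. The 20 genes with the highest mean levels included many germ cell genes. Among them were Prm2 at 13.22 ± 0.04 (n = 3) and Prm1 at 12.72 ± 0.01, the protamines that replace histones on sperm DNA, and Tnp1, a transition protein, at 12.64 ± 0.11. Smcp, a protein of the sperm mitochondrial capsule, was at 12.97 ± 0.04, and Fabp9, a fatty acid binding protein of testis, at 12.98 ± 0.13. Ldhc, the germ cell lactate dehydrogenase, was at 12.92 ± 0.06, the sperm surface protein gene Spa17 at 12.96 ± 0.14 and the lactate and pyruvate transporter gene Slc16a7 at 12.66 ± 0.10. General genes stood there too, among them the translation elongation factor gene Eef1a1 at 13.11 with tied values, the ribosomal protein gene Rpl4 at 12.76 ± 0.06, Ldha at 12.73 ± 0.06 and Hsp90aa1 at 12.61 ± 0.12. The count of genes above background depended on the level chosen. It was 3847 at the 99th percentile of the same families and 10958 with the 95th percentile of olfactory receptor genes.

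Markers of haploid cells were far above background. All 20 genes of the elongating spermatid list were above it, with a list mean of 11.53 ± 0.04 (n = 3), against 7.65 for all named genes. In the round spermatid list 18 of 20 genes were above background and the list mean was 10.57 ± 0.03. The highest round spermatid genes were Spata16 at 12.29 ± 0.01 and Acrv1 at 12.07 ± 0.02, both acrosomal genes, the testis-specific kinase gene Tssk2 at 11.79 ± 0.01 and the acrosomal membrane gene Spaca1 at 11.78 ± 0.03. The lowest were the X-linked gene Tsga8 at 7.96 with tied values and Tssk6 at 7.43 ± 0.10, neither called above background. The lowest genes of the elongating list were Prm3 at 9.53 and Fscn3 at 9.06, both with tied values. Each list was higher than random lists of named genes (adjusted p = 1.83e-05 for each, permutation test). The round spermatid list was 0.96 ± 0.01 lower than the elongating list (adjusted p = 0.0184, permutation test). That difference compares the levels of different genes and does not give the share of round and elongating cells.

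Genes of germ cell chromatin were above background in 15 of 16 measured members, with a list mean of 10.57 ± 0.03 (n = 3; adjusted p = 1.83e-05, permutation test). Besides the protamines and Tnp1, Tnp2 was at 12.12 ± 0.03 and Prm3 at 9.53. The spermatid linker histone genes Hils1 and H1f7 were at 12.22 ± 0.02 and 11.55 ± 0.08, and the testis linker histone gene H1f6 at 9.07 ± 0.09. The testis core histone genes H2ac1 and H2bc1 were at 10.07 ± 0.0011 and 9.23 ± 0.13. Among short H2A variants, H2al2a was at 11.20 ± 0.02, the X-linked H2al3 at 10.38 ± 0.04 and the X-linked H2ab1 at 8.85 with tied values. H2ab1, on chromosome X and also known as H2A.Lap1, encodes an H2A variant of the testis. The bromodomain gene Brdt was at 9.82 and the chromatin remodeller gene Chd5 at 9.91 ± 0.03. Ctcfl, the testis paralog of Ctcf, was at 6.65 and not above background. Near-identical copies of the short H2A variants can share probes, so the levels of H2ab1, H2al2a and H2al3 are uncertain.

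General histone variants were above background in 4 of 9 measured members. The list mean of 8.43 ± 0.02 (n = 3) exceeded that of all genes by 0.78, which did not pass (adjusted p = 0.269, permutation test). H2az1, the H2A.Z gene, was at 12.00 ± 0.02, the macroH2A gene Macroh2a1 at 9.47, H2az2 at 8.70 and Macroh2a2 at 8.35 ± 0.19, the last not called. The centromere histone gene Cenpa was at 6.73 and not above background. The probe set that names only H3f3a was at 7.06 ± 0.01, but with the probe sets it shares with other genes added the value was 11.15, so the level of H3f3a is uncertain. The germ cell chromatin list was 2.14 ± 0.02 higher than this list (adjusted p = 0.00892, permutation test), but this call rested on the probe sets used. With probe sets of several genes added, an alternative for pairs chosen after seeing the data, the difference was 0.83 and did not pass (adjusted p = 0.217, permutation test, from 0.00907 to 0.217 over its alternatives), nor did the difference of list medians of 1.91 (adjusted p = 0.0782, permutation test). With those probe sets the general list mean exceeded that of all genes by 1.81 (adjusted p = 0.00223, permutation test), and the count of 4 members was 7 with the olfactory receptor background and 2 by mean level at the 99th percentile.

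Genes of spermatocytes, the germ cells in meiosis, were above background too. This held for all 18 pachytene spermatocyte genes, with a list mean of 11.05 ± 0.05 (n = 3). The highest were Ldhc at 12.92 ± 0.06, Adam3 at 12.49 ± 0.13, the glycolytic gene Pgk2 at 12.34 ± 0.08 and the chaperone gene Clgn at 12.12 ± 0.05, and the lowest were Tcfl5 at 9.68 ± 0.14 and H1f6 at 9.07 ± 0.09. Several of these genes are also transcribed in spermatids. The round spermatid list lay 0.48 ± 0.02 below the pachytene list, a difference that did not pass (adjusted p = 0.218, permutation test). Of 19 meiotic prophase genes 14 were above background, with a list mean of 9.47 ± 0.08 (adjusted p = 1.83e-05, permutation test). Its highest genes were the cohesin gene Smc1b at 12.04 ± 0.05, the synaptonemal complex genes Sycp2 at 11.70 ± 0.11 and Sycp3 at 11.29 ± 0.19, and the cohesin gene Stag3 at 11.22. Msh5 at 7.26 ± 0.03 and Mei1 at 7.08 were lowest and not above background. The pachytene list was 1.59 ± 0.04 higher than the meiotic prophase list (adjusted p = 0.00231, permutation test). At the 99th percentile background level, 8 of the 19 meiotic prophase genes had a mean above the level. Among genes above background only, the meiotic prophase excess over other genes was 0.48 and did not pass (adjusted p = 0.155, permutation test, from 3.67e-05 to 0.155 over its alternatives).

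Most markers of spermatogonia, the mitotic germ cells, were not called above background. The list mean lay below the level of 7.98 but above the background families' median of 4.77. Of 20 genes 4 were above the level: Dmrtb1 at 8.86 ± 0.03, Id4 at 8.59 ± 0.02, Sohlh2 at 8.27 and Kit at 8.24 ± 0.04. The lowest were Nanos2 at 6.59 and Cdh1 at 6.34, with tied values. The list mean of 7.45 ± 0.01 (n = 3) differed from that of all genes by -0.20, which did not pass (adjusted p = 0.723, permutation test). It was 1.06 ± 0.02 higher than that of genes of other tissues (adjusted p = 0.000234, permutation test). The meiotic prophase list was 2.01 ± 0.09 higher than the spermatogonia list and the round spermatid list 3.12 ± 0.04 higher (adjusted p = 3.25e-05 for each, permutation test). The count of 4 moved to 13 with the olfactory receptor background and to 0 at the 99th percentile level.

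Functional groups of sperm formation were above background in nearly every measured member. This held for all 23 genes of flagellum and sperm channels (list mean 10.97 ± 0.05, n = 3), all 19 of acrosome and fertilization (11.07 ± 0.05) and all 16 of sperm energy metabolism (11.26 ± 0.04). It held for 16 of 17 piRNA and chromatoid body genes (10.28 ± 0.05) and 11 of 12 transcription regulators of spermiogenesis (10.19 ± 0.05). Each of these 5 lists was higher than random lists (adjusted p = 1.83e-05, permutation test). In the flagellum list Odf2 and Odf1, genes of the outer dense fibres, were at 12.46 ± 0.05 and 12.33 ± 0.04, Rsph1 at 12.08 ± 0.03 and Tekt2 at 12.05 ± 0.01. The acrosome list was led by Crisp2 at 12.51 ± 0.15 and Adam3, and its lowest genes were Gopc at 9.41 ± 0.04 and Spaca3 at 8.83. In the energy list the cytochrome oxidase subunit gene Cox8c was at 12.68 with tied values, and the lowest members were Slc25a31 at 9.73 ± 0.12 and Eno4 at 9.48. The piRNA factor gene Mael was at 12.36 ± 0.09 and the RNA helicase genes Ddx4 and Ddx25 at 12.01 ± 0.13 and 11.81 ± 0.10. Piwil4, a Piwi gene of prospermatogonia, was at 6.33 and not above background. Among regulators, Fhl5, a coactivator of CREM, was at 11.66 ± 0.02 and Gtf2a1l at 11.32 ± 0.10, and Sox5 at 7.83 was not above background. Some genes belong to more than 1 of these lists, so the lists are not independent.

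Genes of Leydig and Sertoli cells, somatic cells of the testis, were also above background. In the Leydig list, which holds the steroid-producing interstitial cells' genes, 9 of 11 measured members were above background and the list mean was 9.62 ± 0.07 (n = 3; adjusted p = 0.000406, permutation test). The steroid synthesis genes Cyp17a1 and Hsd3b6 were at 11.36 ± 0.06 and 11.27 ± 0.15, Fdx1 at 10.44 ± 0.09 and Hsd17b3 at 10.39 with tied values. Nr5a1 at 7.69 and Sult1e1 at 7.58 ± 0.18 were not above background. Among genes above background only, the Leydig excess over other genes was 0.50 and did not pass (adjusted p = 0.262, permutation test, from 0.000508 to 0.262 over its alternatives). In the Sertoli cell list 12 of 19 genes were above background, with a mean of 8.56 ± 0.01 (adjusted p = 0.0425, permutation test). Its highest genes were the cystatin gene Cst12 at 11.81 ± 0.04, the protease gene Ctsl at 11.37 ± 0.01, Clu at 11.24 and Aard at 9.88 ± 0.10, while Krt18 at 6.54 ± 0.02 and Amh at 5.91 were lowest. The call for the Sertoli list ended with the highest probe set per gene (adjusted p = 0.0544, permutation test) and with list medians (adjusted p = 0.0574, permutation test). Among genes above background only its excess turned to -0.18 (adjusted p = 0.668, permutation test, from 0.0367 to 0.668 over its alternatives). Of peritubular, endothelial and stromal genes 6 of 16 were above background, with Dcn at 11.16 ± 0.02, Acta2 at 9.37 ± 0.08, Myh11 at 8.72 ± 0.10 and Pdgfra at 8.60 ± 0.20 highest and Kdr at 6.63 and Lum at 5.80 lowest. Of blood and immune genes 4 of 14 were, namely Mrc1 at 9.67 ± 0.09, Lyz2 at 9.55 ± 0.09, Fcgr3 at 8.23 ± 0.10 and Cd68 at 8.16 ± 0.05. The means of these last lists differed from that of all genes by 0.16 and -0.08, which did not pass (adjusted p = 0.754 and 0.866, permutation test). At the 99th percentile background level, the mean lay above the level for 5 Sertoli, 2 peritubular, endothelial and stromal, and 2 blood and immune genes. With the olfactory receptor background, 15, 11 and 8 of these genes were called by limma's adjusted test.

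None of the 20 measured genes of other tissues was above background, by limma's adjusted test, at an unadjusted p under 0.05, or by asking for all 3 arrays above the level. Their mean was 6.39 ± 0.03 (n = 3), lower than random lists (adjusted p = 0.00291, permutation test). The highest were the lens gene Cryaa at 7.87 and the muscle gene Ckm at 7.43 ± 0.06, and the lowest Neurod1 at 5.01 and Scgb1a1 at 4.96. With the lower olfactory receptor background 4 of them were called. Compared with this list, the Leydig list was 3.23 ± 0.10 higher and the Sertoli list 2.17 ± 0.02 higher (adjusted p = 3.25e-05 for each, permutation test). The peritubular, endothelial and stromal list was 1.42 ± 0.05 higher (adjusted p = 0.000316, permutation test) and the blood and immune list 1.18 ± 0.03 higher (adjusted p = 0.00119, permutation test). The round spermatid list was 2.02 ± 0.04 higher than the Sertoli list (adjusted p = 0.000316, permutation test). Its mean exceeded that of the Leydig list by 0.95 ± 0.05, which did not pass (adjusted p = 0.0602, permutation test), and by 0.31 with the steroid synthesis genes alone (p = 0.559, permutation test). With probe sets of several genes added it was 1.05 higher (adjusted p = 0.0361, permutation test), and both of these alternatives were chosen after seeing the data. Housekeeping genes had a mean of 10.50 ± 0.03 with 12 of 13 above background, from Eef1a1, Actb at 11.91 ± 0.03, Eef2 at 11.63 ± 0.01 and Tbp at 11.45 ± 0.06 down to Pgk1 at 8.88 and Gusb at 7.71, the last not above background.

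**Figure D1:**
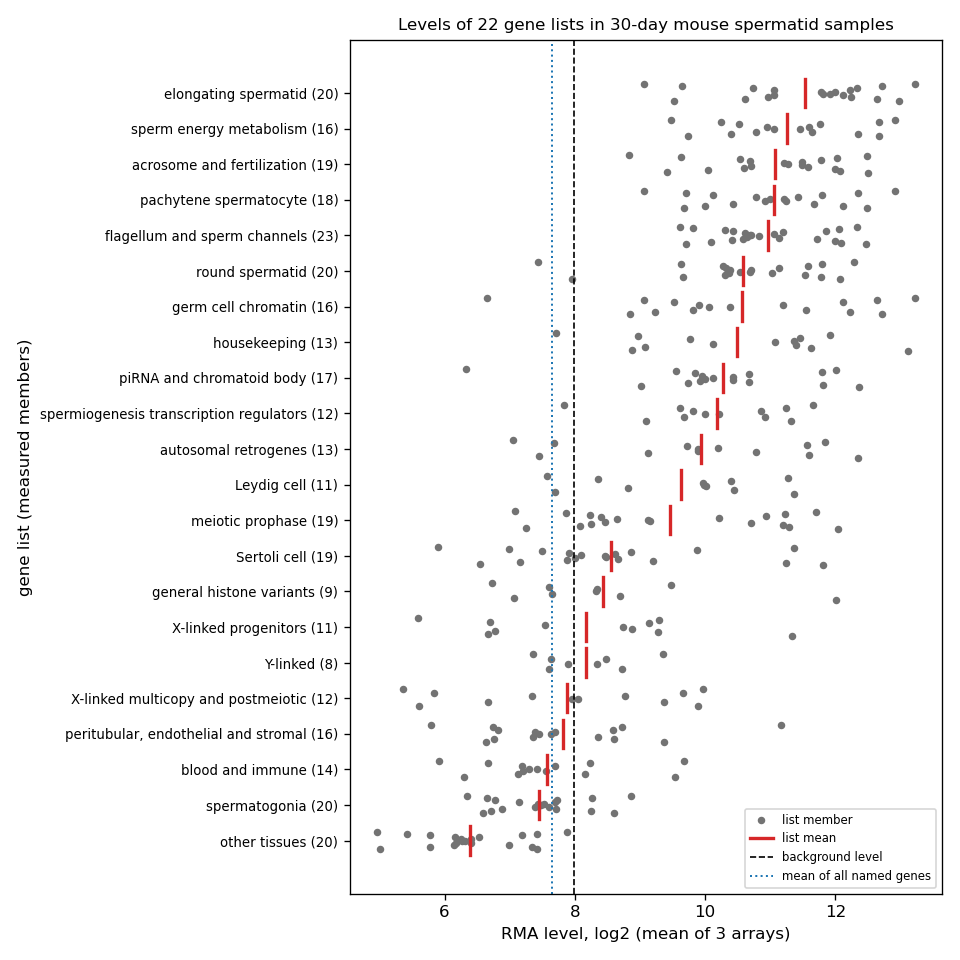
Mean RMA level (log2, horizontal axis) of each measured member (grey points) of 22 gene lists, with the list mean (red bar), the background level of 7.98 (dashed line) and the mean of all named genes of 7.65 (dotted line); points are offset vertically within a list only to separate them. The elongating spermatid list has the highest mean at 11.53 and the list of other tissues the lowest at 6.39, with all of its 20 members left of the background level.

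The counts of list members above background, adjusted over the list alone, were 16 of 19 for meiotic prophase and 3 of 14 for blood and immune genes, and equal to the counts over all genes for the other 20 lists.

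X-linked genes were lower than autosomal genes, a comparison of interest because the sex chromosomes are silenced during meiosis and only partly transcribed afterwards. The mean level of 739 X-linked genes was 7.18, against 7.67 for 19106 autosomal genes, a difference of -0.49 ± 0.01 (n = 3; p = 1e-05, the smallest the permutation test can give). Of X-linked genes 27.6% were above background and of autosomal genes 37.0% (p = 1e-05, permutation test). Among the autosomes, chromosome 7 had the lowest share, 28.5%, and chromosome 18 the highest, 42.0%, and on chromosome Y 2 of 9 genes (22.2%) were above background. Among genes above background the difference was -0.30 (p = 0.00012, permutation test), from means of 9.28 for 204 X-linked and 9.58 for 7068 autosomal genes. The difference of medians was -0.32 (p = 4e-05, permutation test), and without vomeronasal and olfactory receptor and hair keratin associated protein genes the difference of means was -0.64 (p = 1e-05, permutation test). Chromosomes were taken for each gene from assembly GRCm38.p6, not from the position of its probe sets. Levels of some X-linked genes may therefore not come from chromosome X alone, which was not tested.

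**Figure D2:**
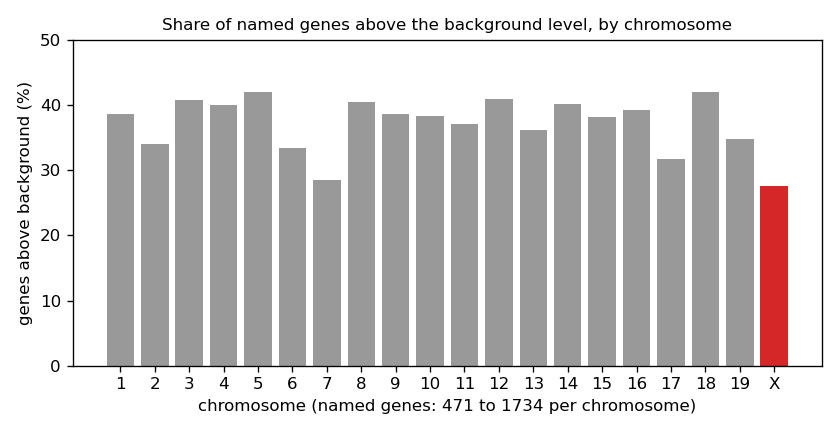
Share of named genes above the background level (%, vertical axis) on each of the 19 autosomes (grey bars) and on chromosome X (red bar). Of the chromosomes drawn, X has the lowest share at 27.6% and chromosome 7 the next lowest at 28.5%.

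Within chromosome X, 5 of 12 measured genes of the multicopy and postmeiotic list were above background. Tcp11x2 was at 9.96 ± 0.04, Cypt2 at 9.88 ± 0.06, Actrt1 at 9.67 and Cypt1 at 9.37 ± 0.03, while Magea6 at 5.61 and Magea5 at 5.36 ± 0.25 were lowest. The list mean exceeded that of the other 727 X-linked genes by 0.71 ± 0.03, which did not pass (p = 0.148, permutation test). Its excess of 0.22 over all genes also did not pass (adjusted p = 0.739, permutation test). The count of 5 was 8 with the olfactory receptor background. Another 11 listed genes had no probe set of their own. With probe sets that name several genes added, 20 members had a value, some of them the same value from a common probe set, and the list exceeded all genes by 0.95 (adjusted p = 0.0246, permutation test). Of 8 measured Y-linked genes 2 were above background, the translation initiation factor gene Eif2s3y at 9.35 ± 0.12 and the sex-determining gene Sry at 8.48 ± 0.02. The zinc finger genes Zfy1 and Zfy2 were at 8.72 ± 0.34 and 8.34 ± 0.22 and were not called by limma's adjusted test, though 4 of the 8 genes passed at an unadjusted p under 0.05, and Kdm5d at 7.61 ± 0.06 and Uba1y at 7.36 ± 0.17 were lowest. The count of 2 was 7 with the olfactory receptor background and 1 by mean level at the 99th percentile. The Y-linked list exceeded all genes by 0.52, which did not pass (adjusted p = 0.51, permutation test). With probe sets of several genes added it exceeded all genes by 1.15 (adjusted p = 0.0424, permutation test).

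Autosomal retrogenes, copies of X-linked genes that were inserted on autosomes, were high as a list. Of 13 measured retrogenes 10 were above background, with a mean of 9.93 ± 0.05 (n = 3; adjusted p = 1.83e-05, permutation test), and of 11 X-linked progenitors 6 were, with a mean of 8.18 ± 0.04 (adjusted p = 0.439, permutation test). In 10 pairs with a value on each side, the retrogene was higher in 7 and the mean difference was 1.34, with an SD over pairs of 2.65. This difference did not pass (p = 0.145, two-sided exact sign-flip permutation test, smallest possible p 0.00195). With probe sets of several genes added, an alternative chosen after seeing the data, the retrogene was higher in 8 of 12 pairs. The mean difference there was 1.23 and did not pass (p = 0.13, sign-flip permutation test). Rbmx moved from 6.78 to 9.33 with those probe sets, which placed it above its retrogene Rbmxl2 at 7.68. Pgk2 was at 12.34 ± 0.08 and its progenitor Pgk1 at 8.88, Pdha2 at 10.78 ± 0.02 and Pdha1 at 7.54, Cetn1 at 10.20 ± 0.25 and Cetn2 at 6.67 ± 0.06, and Mcts2 at 11.60 and Mcts1 at 5.59 ± 0.15. In the opposite direction, Rpl10l was at 9.89 ± 0.09 and Rpl10 at 11.33 ± 0.01, Zfa-ps at 7.44 ± 0.17 and Zfx at 8.74 ± 0.11, and Cstf2t at 7.05 and Cstf2 at 9.27. At the 99th percentile level 3 of the 11 progenitors had a mean above the level. Probe binding differs between the members of a pair, and a retrogene can share probe targets with its progenitor, so single pairs are uncertain. A probe set of Pgk1 is numbered among those of chromosome 12 genes, and a probe set of Rpl10 among those of chromosome 19 genes. The levels of these progenitors may therefore not come from the X-linked genes alone, which was not tested.

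By medians, the meiotic prophase, Y-linked and Leydig cell lists lay outside the central 95% of random lists of the same level in more than 1 replicate each. Shifts of other lists could be as large without lying outside it. The median meiotic prophase gene was 0.05 lower in replicate 2 than in the mean of the other arrays and 0.09 higher in replicate 3, at percentiles 2.16 and 99.8 of random lists of the same level. The median Y-linked gene was 0.14 lower in replicate 2 and 0.15 higher in replicate 3, at percentiles 0.03 and 99.98. The median Leydig cell gene was 0.09 higher in replicate 1, outside the central 95% of 10000 random lists (mean shift 0.08, percentile 99.97), and 0.10 lower in replicate 2, at percentile 0.63. By medians, the flagellum, sperm energy and retrogene lists also lay outside the central 95% in replicate 1, at percentiles 99.8, 97.8 and 1.6, with shifts of 0.01, 0.0032 and -0.02. By means the retrogene list stayed outside, at percentile 1.0, while the flagellum and sperm energy lists lay inside at percentiles 76.8 and 78.6 with shifts of the opposite sign. The round and elongating spermatid lists lay within the central 95% by medians in each replicate. By means, 3 further lists lay outside: round spermatid genes in replicate 1 (0.01, percentile 98.6), peritubular, endothelial and stromal genes in replicate 1 (0.02, percentile 99.4) and X-linked multicopy genes in replicate 3 (0.08, percentile 98.1). Of 66 combinations of list and replicate 9 lay outside the central 95%, where 3.3 would by chance, though lists share genes and the shifts of 1 list over the replicates are tied together. These percentiles describe the 3 arrays and are not tests between conditions. No gene called above background by limma spanned more than 1 over the arrays, but that test divides by the SD and so leaves out genes that vary. By mean level alone, 2 genes did, named here after their values were seen. Spink8 was at 7.37, 8.68 and 10.23 in replicates 1, 2 and 3, and Cuzd1 at 7.64, 8.30 and 9.45. Among probe sets above the background level, 42 differed by more than 1 between replicates 2 and 3. The largest SDs among called genes were 0.43 for Rbm12b2 at a mean of 9.45, 0.40 for Pate11 at 9.07, 0.40 for Zfp105 at 9.41 and 0.39 for Prp2 at 9.34.

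**Figure D3:**
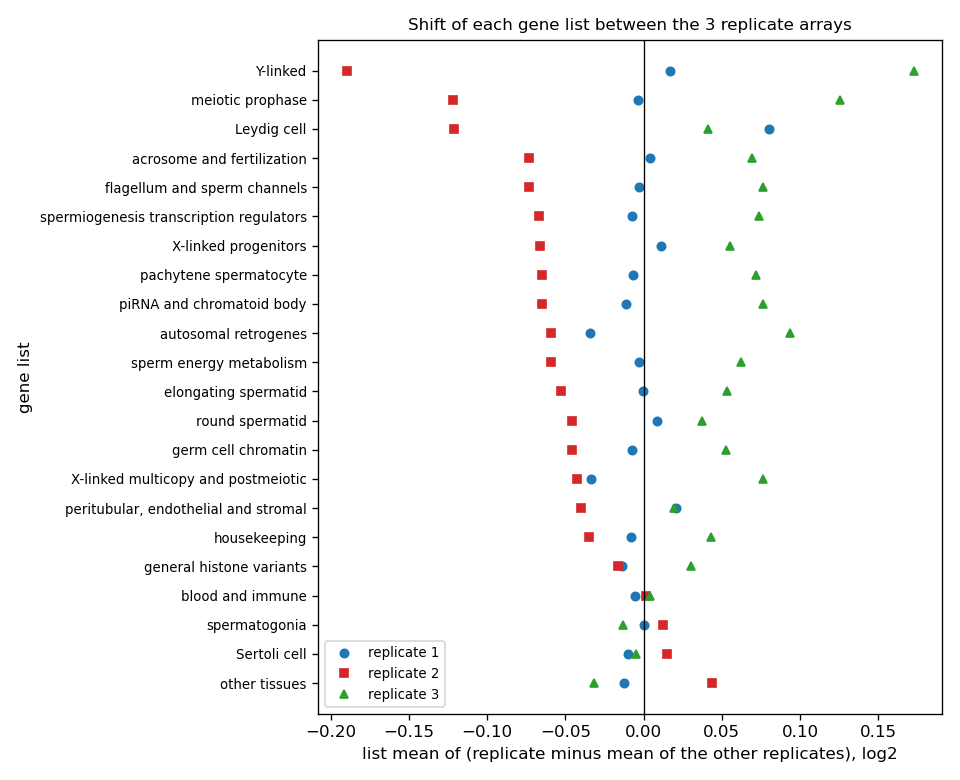
Mean over list members of the level in 1 replicate minus the mean of the other replicates (log2, horizontal axis) for 22 gene lists, with a symbol for each replicate array; means were chosen after ties had made 25 of the medians exactly 0. Replicate 2 lies lowest and replicate 3 highest for most germ cell lists, from -0.19 to 0.17 for the Y-linked list, and replicate 1 lies highest for the Leydig cell list at 0.08. The housekeeping list shifted the same way as most germ cell lists, by -0.03 in replicate 2 and 0.04 in replicate 3. Most germ cell shifts by means lay within the central 95% of random lists of the same level.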

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

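Alternatives chosen after seeing the data were the raised SD of tied genes, list means of the replicate shifts, genes of 1 probe set, steroid synthesis genes alone, sets of genes that share probe sets, such probe sets in list pairs and retrogene pairs, and a count of varying genes by mean level. Of 280 values recomputed under an alternative, 265 kept their call, or stayed within 1 SD or, for counts, within 1.5 times. Correlations between arrays were instead held to the range of the 3 pairwise values. A common median or leaving out a replicate could not take them out of that range. The recomputed values all come from the same 3 arrays and are not independent. The count of genes above background depended on the background level, with 3847 genes at the 99th percentile and 10958 with olfactory receptors against 7295. It ranged from 6662 to 7090 when a replicate was left out, and was 6850 with the SD of tied genes raised to the median of untied genes. The lowest correlation between arrays was 0.986 over probe sets above background, against 0.992 over all, a narrower range of levels by construction, and 0.992 to 0.995 when a replicate was left out. Among genes above background only, a filter that by construction drops the low members of a list, the excess over other genes was 0.48 for meiotic prophase (adjusted p = 0.155) and 0.50 for Leydig cell genes (adjusted p = 0.262), and it reversed to -0.18 for Sertoli cell genes (adjusted p = 0.668), each by permutation test. Over all their alternatives the adjusted p ranged from 3.67e-05 to 0.155, 0.000508 to 0.262 and, for Sertoli genes, 0.0367 to 0.668. The Sertoli excess was 0.88 with the highest probe set and 1.02 with the list median, neither past the threshold. The cause of those 2 changes was not tested. With probe sets of several genes added, 3 lists came past the threshold, at an excess of 1.81 for general histone variants (1 member added, 3 changed in value), 0.95 for the X-linked multicopy list (8 added, 4 changed) and 1.15 for Y-linked genes (3 added). Members that share a probe set carry the same value there and are not independent, and over all alternatives their adjusted p ranged from 0.00223 to 0.934, 0.0246 to 0.934 and 0.0424 to 0.568. The X-linked multicopy excess, not past the threshold, was -0.04 among genes above background. The germ cell chromatin list exceeded general histone variants by 0.83 with those probe sets, which lowered the first list and raised the second, and by 1.91 in medians, where the cause was not tested, neither past the threshold (adjusted p from 0.00907 to 0.217 over the alternatives). The round spermatid list exceeded the Leydig list by 1.05 with those probe sets, past the threshold (adjusted p from 0.0361 to 0.0988 over the alternatives, permutation test). With the steroid synthesis genes alone the p was 0.559 (permutation test), not adjusted over the pairs. By mean level, with no test that by construction drops variable genes, 2 genes above the level varied by more than 1, against 0. The genes of other tissues had no member left above background, so that filter gave no value for them. Leaving out each replicate ended no call for a list, a list pair, X against autosomes or retrogenes. No paired analysis was possible because there is only 1 group. Genes with levels near the background level, such as many spermatogonia genes, change their call with the level chosen.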

Other observations

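Tests in this part on gene families, on array duplication, on Leydig and Sertoli cell genes and on X-linked genes that share probe sets were chosen after the levels had been seen. Gene families formed from the letters of the symbol gave a wider view of the RNA. Of 142 families with at least 15 named genes, 44 were higher and 32 lower than random lists (Benjamini-Hochberg adjusted permutation test at 0.05). The highest means were those of the Spata family, genes associated with spermatogenesis, at 10.21 with 25 of 29 above background, and of the Cfap family of cilia and flagella proteins at 10.18 with 29 of 31. Nucleoporin genes (Nup) followed at 9.94 with 18 of 20, centrosomal genes (Cep) at 9.61 with 30 of 37 and Dnajc chaperone genes at 9.57 with 25 of 28, beside ribosomal protein genes (Rpl) at 9.90 with 29 of 36. Ubiquitin-conjugating enzyme genes (Ube) stood at 9.41 with 30 of 39 and deubiquitinase genes (Usp) at 8.92 with 37 of 55. The adjusted p was 4.06e-05 for each of these families. At the low end were the prolactin family (Prl) at 4.81 with 0 of 19 above background, taste receptors (Tas) at 5.18 with 0 of 37 and sulfotransferases (Sult) at 5.20 with 0 of 16, by limma's adjusted test. Families share a naming history, not always a function.

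A candidate explanation for the many values exactly equal between arrays is the median polish that RMA uses to summarise a probe set, since with 3 arrays the median of each probe is 1 of its own values. In simulated median polish of independent arrays with 25 probes per set, 85.0% of sets were exactly equal in a pair of arrays when the arrays did not truly differ, and 27.3% when they differed by an SD of 0.2, against 38.8% to 51.4% seen here. Over all probe sets the fit is partial. The SD of the difference between arrays was 0.02 and 0.21 in those settings and 0.20 to 0.26 here. At a like spread the simulation thus gave fewer ties, and with 10 probes per set at most 31.0%. Among probe sets above the background level the fit was closer. They had 31.4% to 44.3% ties at SDs of the difference from 0.20 to 0.13. With 25 probes the simulation gave 54.7% at 0.08, for arrays that differed by an SD of 0.1, and 27.3% at 0.21. Deposit of the same array more than once was argued against by the 51.44% of probe sets that were equal in the most similar pair, which leaves the rest different.

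Leydig and Sertoli cell genes lay above background in samples labelled spermatids. Probe background alone was argued against, since 21 of 30 pooled Leydig and Sertoli genes were above background and 0 of 20 genes of other tissues were (one-sided Fisher's exact p = 2.13e-07). RNA of somatic testis cells in the suspension and transcription of the same genes in germ cells both stay open and cannot be told apart. For 12 members, 7 Leydig and 5 Sertoli, the mean exceeded the 99th percentile of the background families, with Cyp17a1 at 11.36 and Cst12 at 11.81 the highest of each list, but either source would give such a count. The described protocol names no step that would remove somatic cells, and 0 sorted germ cell samples were among the samples.

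As the whole source of the lower level of X-linked genes, X-linked families silent in these cells were argued against, since the difference was -0.299 among genes above background only. Multicopy X genes missing from the comparison stay open: adding 43 X-linked and 549 autosomal sets of genes that share probe sets left -0.4227, but so few sets could not have closed the gap, and a test on genes of 1 probe set (-0.50) had the same fault. The added X-linked sets had a mean of 8.17 and 53.5% lay above the background level, against 7.13 and 31.5% for the autosomal sets, opposite in direction to the difference among single genes and not tested. No biological explanation was tested, since the single group holds no separate cell stages. Gene content that differs between chromosomes, and 1 X chromosome copy against 2 of each autosome before meiosis, were not tested.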
